A study of Nicotiana benthamiana with 4 samples.

How the data were processed

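Small RNAs of Nicotiana benthamiana leaves were measured in 2 libraries, each sequenced in 2 runs, which gave 4 files. Per the labels, total RNA was extracted with the miRNeasy Mini kit and libraries were made with the TruSeq small RNA kit. The deposited values are raw read counts of each different trimmed sequence in 1 run, not normalized, as the files show by whole numbers whose totals differ. The trimming tool, the quality filter and the length limits are not given in the sources used here. The reads were not aligned here, and no genome was used, so no loci are given. Each replicate name was taken from the labels, and the runs of a library were summed as technical repeats, so that n = 2.

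The shares by length and 5' base, the family levels and the structural RNA shares were computed per library in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Levels are RPM, read counts scaled to the total of the 18 to 28 nt reads, of which library 1U had 15542241 and 1V 16560315. A read of 20 to 24 nt was given to a family when its first 18 bases equalled those of a listed mature sequence. The list held 39 miRNA families, 9 star strands and tasiR-ARF, plus 7 control families of other organisms. Structural RNAs were 15 sequences under 13 names, matched as exact sense substrings of at least 15 nt. The longest rRNA of the nucleus and that of the plastid were not among them. Both lists were written from general knowledge, so a base that differs in this species makes a level an underestimate. Pairing was the share of reads of 21 to 24 nt whose sequence had a partner of equal length in the same library, at 3' overhangs from -6 to 8 nt.

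Libraries were compared by an exact binomial test of the reads of each family given the library totals, 2-sided, with Benjamini-Hochberg adjustment over the 34 families with at least 10 reads and a threshold of 0.05, and runs were compared by the same test. The intervals of the folds are exact Clopper-Pearson 95% intervals, and 0 reads were taken to allow 3 reads. With 1 group, edgeR's quasi-likelihood test had no contrast. The biological coefficient of variation came from the common dispersion of edgeR 4.0.16 in R 4.3.3 after TMM, over families or sequences with at least 50 reads. TMM and the size factors of DESeq2 1.42.0 served as other scalings. Agreement of runs was the Pearson chi-square per degree of freedom over sequences with at least 50 reads.

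The 2 main lists and the rule for named families were fixed before the data were examined. So were the tests, other than those of the flagged patterns, and the alternatives, other than those named as added. The rule named every listed family or star strand with a mean of at least 100 RPM, those over 2-fold apart with at least 50 reads in a library, the 3 most abundant sequences of 21, 22, 23 and 24 nt, and every structural RNA. It named 15 families and star strands. Other names in the text were chosen after their values were seen. The added alternatives were the coefficient of variation without 3 families, 5' overhangs as the background of pairing, and 2 more plastid tRNAs. The other alternatives were the counting of different sequences, single runs, other length windows, match rules, read minimums, depths and scalings, and each library alone.

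The steps were tested on simulated data. Of 200 simulated 2-fold changes among 5000 sequences, the binomial test recovered 64%, and it recovered 100% of the 22 with at least 400 reads. It called 0.125% of the unchanged sequences. The simulated counts held counting error alone, so these rates do not carry over to the real libraries. There the chi-square per degree of freedom was 26.8. The pairing measure returned 30.0% of simulated partners at a 2-nt overhang where 30.0% had been put in, at 21 and at 24 nt. Simulated coefficients of variation of 0.1 and 0.3 came back as 0.108 and 0.323 over 33 families, and as 0.101 and 0.298 over 17836 sequences of 24 nt.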

Results

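Small RNAs were sequenced from leaves of uninoculated wild-type Nicotiana benthamiana plants. The series held 1 group of 2 biological libraries, named 1U and 1V, and each library was sequenced in 2 runs. Library 1U gave 30027271 reads, from 13859162 and 16168109 reads per run. Library 1V gave 33287682 reads, from 15373285 and 17914397 reads per run. The reads were 15 to 42 nt long and held 8628613 different sequences, of which 1266617 occurred in both libraries. Means are given with the SD over the 2 libraries (n = 2), after the runs of a library were summed. No treatment or second group exists, so every comparison is between size classes, RNA classes or the 2 libraries. PCR reads without molecular identifiers are not independent molecules, so the intervals, limits and p-values given cover counting error only.

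The size distribution addressed which small RNA classes leaves accumulate. The 24-nt class, in plants mainly the heterochromatic siRNAs that guide DNA methylation, took 19.2% ± 0.107 of all reads. The 21-nt class, which holds most miRNAs, took 7.78% ± 0.290. The 22-nt and 23-nt classes took 5.61% ± 0.0354 and 6.47% ± 0.0960. The 24-nt class was far more diverse, with 52.7% ± 0.0420 of the different sequences of a library against 5.86% ± 0.262 at 21 nt. The 23-nt class was second by different sequences, with 13.2% ± 0.178. The 24-nt reads outnumbered the 21-nt reads by 2.55 times in library 1U and 2.40 times in 1V. That ratio was 9.01 when each different sequence counted once, and 1.21 among sequences with at least 5 reads in both libraries. The most frequent length by reads was 15 nt, the shortest length present, with 23.7% ± 2.49. A single 15-nt sequence, CCCGGCCGTCGGGGC, made up 18.2% ± 2.93 of all reads, and it matched none of the listed RNAs.

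**Figure D1:**
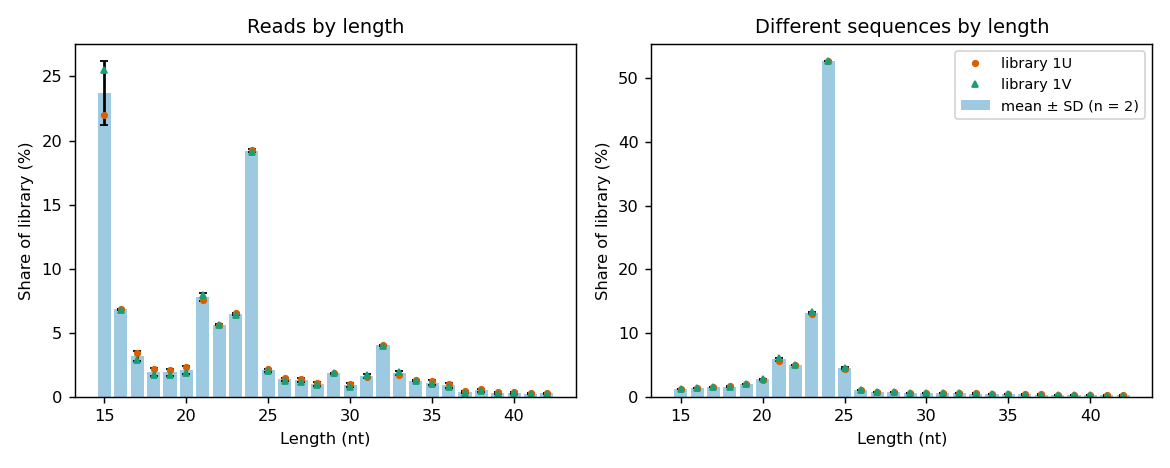
Share of each library (%) by length (nt) for reads (left) and different sequences (right), with bars as the mean of libraries 1U and 1V, error bars as SD and points as single libraries. The 24-nt class holds 19.2% of reads and 52.7% of different sequences.

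The 5' base, which affects the Argonaute protein a plant small RNA enters, differed between the size classes. A opened 61.7% ± 0.304 of the 24-nt reads and 57.5% ± 0.811 of the different 24-nt sequences. T, for U in RNA, opened 61.6% ± 4.98 of the 21-nt reads. Without the listed miRNAs and structural RNAs, T opened 39.5% ± 4.504 of the 21-nt reads, and it opened 37.1% ± 0.592 of the different 21-nt sequences. The 22-nt reads began with T in 38.6% ± 0.855 and with A in 32.03% ± 2.36 of cases, and without the listed RNAs with A in 36.6% ± 2.70 and T in 30.8% ± 0.817. The most abundant 22-nt sequence, which starts with A and matched no listed RNA, made up 19.4% ± 3.32 of the 22-nt reads. Among the different 22-nt sequences T led, with 38.2% ± 0.485 against 27.2% ± 0.158 for A. C opened 44.4% ± 1.13 of the 23-nt reads, and 19.9% ± 0.0585 without the listed RNAs, since 1 plastid rRNA fragment that starts with C made up 30.7% ± 1.39 of that class. The 24-nt preference for A held in both libraries, at 61.9% in 1U and 61.5% in 1V.

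**Figure D2:**
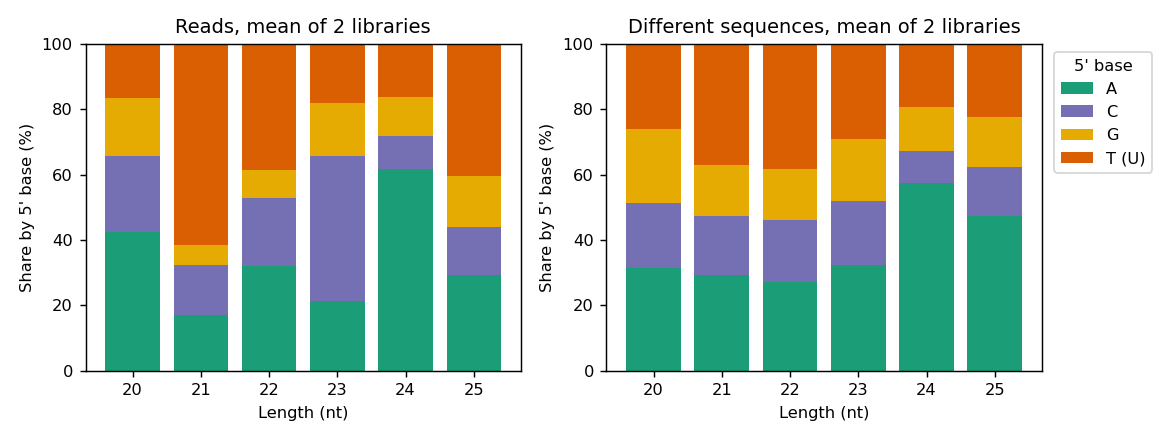
Share (%) of reads (left) and of different sequences (right) with each 5' base, by length from 20 to 25 nt, as means of the 2 libraries. A leads at 24 nt by both measures, with 61.7% of reads and 57.5% of sequences, while the T share at 21 nt falls from 61.6% of reads to 37.1% of sequences.

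The comparison of libraries and runs asked how far the small RNAs of 1 leaf sample recur in another. With the libraries thinned to 4999033 and 5003958 reads, 85.6% ± 0.211 of the 21-nt reads of a library had a sequence that also occurred in the other library. For 24-nt reads the share was 45.8% ± 0.00470. Between the 2 runs of the same library, at the same depth, the shares were 85.9% ± 0.00486 at 21 nt and 47.1% ± 0.183 at 24 nt. The SD of a share between libraries comes from the 2 directions of 1 comparison, so it is not a spread between replicates. At 24 nt the gap between these shares was small beside the shares. Whether it exceeds the variation of replicates was not tested. The 24-nt share was 63.7% ± 0.481 without thinning and 30.3% ± 0.0309 at 999226 and 999839 reads. Over sequences with at least 50 reads, the chi-square per degree of freedom was 2.43 between the runs of 1U, 2.93 between those of 1V and 26.8 between the libraries, where the runs hold technical noise alone. At 24 nt the values were 1.12, 1.11 and 4.61, close to counting error between runs. The biological coefficient of variation was 0.184 for 24-nt sequences, 0.281 for 21-nt sequences and 0.342 for the listed families. For the families it was 0.162 without miR397, miR398 and miR408.

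The abundance of miRNA families addressed which conserved and Solanaceae regulators dominate in leaves. Listed miRNAs made up 6.91% ± 1.11 of the 18 to 28 nt reads and 41.9% ± 4.01 of the 21-nt reads. miR166, which targets HD-ZIP III transcription factors, was the most abundant family with 47712 ± 8414 RPM (normalised read count, scaled to the 18 to 28 nt reads), or 69.0% ± 1.07 of the miRNA reads. miR159, which targets MYB factors, followed with 5924 ± 1159 RPM. miR6149, of the Solanaceae list, reached 3962 ± 792. miR168, which targets AGO1, reached 3687 ± 727, and miR403, which targets AGO2, reached 1354 ± 185. miR396, which targets growth-regulating factors, reached 3011 ± 168. miR157 and miR156, which target SPL factors, reached 1101 ± 188 and 324 ± 12.01. miR398, which targets copper/zinc superoxide dismutases, reached 688 ± 610. miR482, which targets NLR immune receptors, reached 395 ± 112, and miR167, which targets auxin response factors, reached 236 ± 24.2. miR408, which targets copper proteins of the plantacyanin type, reached 115 ± 81.6. miR319, which targets TCP factors, and miR397, which targets laccases, reached 35.5 ± 21.7 and 28.6 ± 20.4. Of the listed miRNA families, 23 of 27 conserved and 6 of 12 NLR-targeting or Solanaceae families had at least 10 reads. Of the 49 listed families and star strands, 13 had 0 reads, among them miR394 and miR828, which allows up to 0.193 RPM in 1U and 0.181 in 1V for the exact listed 18 bases. That limit does not cover forms with another base, and the miR160 star, with 0 exact reads, had reads with up to 1 mismatch.

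Of the 34 listed families tested, 30 lay within 2-fold between the 2 libraries and 4 differed by more. Differences of that size were not rare among single 21-nt sequences. Between the libraries, 13.99% of those with at least 50 reads and 12.6% of those with at least 200 reads were over 2-fold apart. miR398, miR397 and miR408, which all target copper proteins, were lower in 1V than in 1U. miR398 had 1120 RPM in 1U and 257 in 1V, a 4.36-fold difference (95% exact binomial interval 4.21 to 4.51). miR397 had 42.98 and 14.1, a 3.04-fold difference (2.62 to 3.55, adjusted p = 9.44e-55 by the exact binomial test). miR408 had 173 and 57.2, a 3.02-fold difference (2.80 to 3.25, adjusted p = 6.93e-214 by the exact binomial test). miR319 was higher in 1V, at 50.8 against 20.1 RPM, a 2.52-fold difference (2.21 to 2.88, adjusted p = 8.04e-49 by the exact binomial test). The log2 change of miR319 was below 2-fold under TMM, at 0.95, and with up to 1 mismatch in the matched bases, at 0.86. With 1 mismatch, a miR159 read without its first base also matches miR319, so the 0.86 may mix the 2 families. Under TMM tasiR-ARF, named after its values were seen, went past 2-fold with a log2 change of -1.27, and under DESeq2 size factors with -1.21 (-0.89 with library totals).

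Over the 34 families tested, the 2-sided exact binomial test with Benjamini-Hochberg adjustment separated the libraries for 29, with 23 higher in 1V and 6 higher in 1U. The same test, used as a negative control, separated the runs for 7 families in each library. It thus calls families even between technical repeats, and a small p-value does not measure the spread between plants. Families were higher in 1V in 28 of 34 cases by library totals, in 14 under TMM and in 17 under DESeq2 size factors, which centre the median of these families at 0. TMM shifted all families by -0.38 on the log2 scale and DESeq2 size factors by -0.32. Relative to those scalings miR167, miR396 and miR403 were lower in 1V, while miR157 and miR166 were lower under TMM alone. Over all tested families, 14 changed sign under TMM and 11 under DESeq2 size factors. The test compares these 2 libraries, not conditions.

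**Figure D3:**
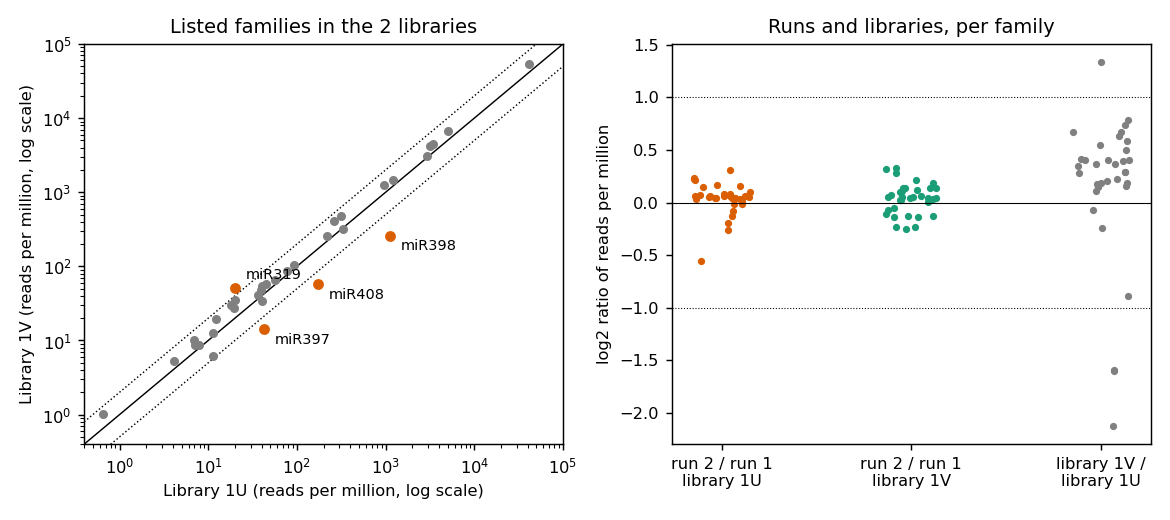
Left, RPM of each tested family in library 1U against 1V on log axes, with lines at equality (solid) and 2-fold (dotted) and the 4 families over 2-fold in orange. Right, log2 ratios per family between runs and between libraries by library totals, with dotted lines at 2-fold; TMM moves the points of the libraries by -0.38, which takes miR319 inside 2-fold, tasiR-ARF outside 2-fold and 14 families below 0, among them miR166.

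The most frequent miRNA length was 21 nt, and lengths varied at the 3' end, since the match fixed the 5' end. Reads of 21 nt made up 93.4% ± 0.0657 of the miRNA reads, most of them miR166, and 20 of the miRNA families tested had 21 nt as their most frequent length. The 22-nt form, which can trigger secondary siRNAs, led in 7 families. miR482 was 22 nt in 97.8% ± 0.480 of its reads. miR168 was 22 nt in 69.3% ± 1.27, with TCGCTTGGTGCAGGTCGGGACC as its most frequent sequence at 64.6% ± 1.98. miR167 was 22 nt in 61.0% ± 4.99 of its reads. miR156 was 20 nt in 94.1% ± 0.591. miR408 and miR319 were mixed, with 42.8% ± 3.98 and 49.8% ± 1.36 of their reads at 21 nt. miR166 was 21 nt in 99.6% ± 0.0453, and TCGGACCAGGCTTCATTCCCC made up 83.2% ± 0.00908 of it. Reads of 20 to 24 nt that held the first 19 bases of miR166 but started upstream of them made up 9.95% ± 0.463 of miR166 and these reads together. Reads that started downstream of its first base were not counted. The star strand of miR168 reached 335 ± 102 RPM, or 8.98% ± 0.990 of miR168. For miR166 the star reads amounted to 0.108% ± 0.00186 of the miRNA, for miR396 to 1.57% ± 0.220 and for miR390 to 23.4% ± 8.91.

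Several of the most abundant sequences belonged to no listed RNA. Since the longest nuclear and plastid rRNAs were not listed, these sequences may still include rRNA fragments. AGTTACTAATTCATGATCTGGC led the 22-nt class with 21475 ± 4404 RPM. Its longer forms AGTTACTAATTCATGATCTGGCA and AGTTACTAATTCATGATCTGGCAT ranked second at 23 nt and 24 nt, with 3218 ± 170 and 1803 ± 338. CCCATTCCCGAACCCGTCGGCT followed at 22 nt with 11600 ± 1679. GCCGGCCGGGGGACGGACTGGGA was the next at 23 nt with 1739 ± 114, and CCACCCCAAGATGAGTGCTCTCCT the next at 24 nt with 565 ± 98.4. At 21 nt the miR166 forms TCGGACCAGGCTTCATTCCCC and TCGGACCAGGCTTCATTCCTC reached 39678 ± 7002 and 7751 ± 1384.

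The pairing of small RNAs within a library addressed whether Dicer products, which leave 2-nt 3' overhangs, could be seen without a genome. At 21 nt, 9.20% ± 0.683 of the reads had a partner at a 2-nt 3' overhang, against 4.11% ± 0.375 at a 2-nt 5' overhang, which pairs as many bases. In 1V the share at a 3-nt 3' overhang, 9.89%, was above its 9.68% at 2 nt, while in 1U it was below, at 6.98% against 8.71%. At 22 nt the shares at 2-nt 3' and 5' overhangs were 11.3% ± 3.45 and 6.53% ± 0.717. At 23 nt they were 6.09% ± 0.370 and 4.20% ± 0.542. Every read of a sequence with a partner counts, so abundant sequences can carry these shares. At 23 nt and a 6-nt 3' overhang the share was 39.4% in 1V and 6.81% in 1U, or 11.6% and 10.2% without the listed RNAs. At 22 nt and a 7-nt 3' overhang, 1V had 12.7%, against 13.7% at 2 nt. The 24-nt siRNAs showed the smallest difference between the 2-nt 3' and 5' overhangs, with 15.3% ± 0.776 and 13.9% ± 0.780. As different sequences, the ratio of the 2 overhangs was 1.27 ± 0.0346 at 21 nt, 1.17 ± 0.0155 at 22 nt, 1.55 ± 0.00291 at 23 nt and 1.11 ± 0.0140 at 24 nt. At 23 nt the ratio did not peak at 2 nt, since it was 1.63 ± 0.00944 at 1 nt and 1.62 ± 0.00552 at 3 nt. The 24-nt class also had 15.3% ± 0.763 of its reads with a blunt-ended partner, against 12.7% ± 0.779 at a 1-nt 3' overhang. Against the median of the other overhangs, the background fixed before the data were examined, the 2-nt share was 1.60 ± 0.0587 times as high at 21 nt and 0.955 ± 0.00293 times at 24 nt. Over different sequences these ratios were 0.992 ± 0.0209 and 0.868 ± 0.00675, so against that background the excess at 21 nt was seen in reads only. The comparison with 5' overhangs was added after the values were seen.

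**Figure D4:**
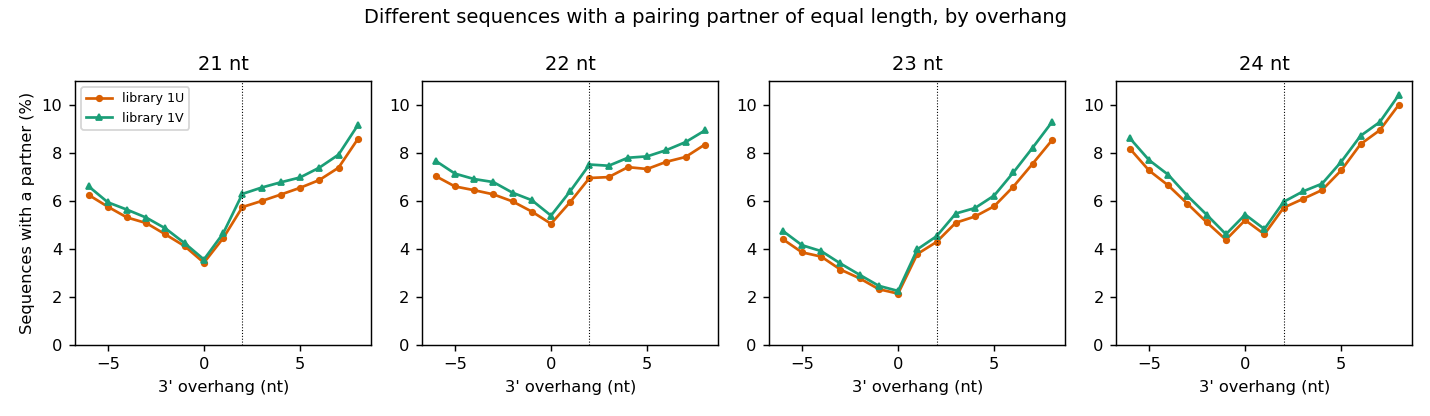
Share (%) of different sequences with a pairing partner of equal length, by 3' overhang (nt, negative values are 5' overhangs), for 21 to 24 nt in libraries 1U and 1V, with a dotted line at 2 nt. The share at 2 nt is 6.02% at 21 nt and 5.84% at 24 nt, and it keeps rising at longer overhangs.

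Fragments of structural RNAs showed which stable RNAs leave defined pieces in leaves. The listed rRNAs, tRNAs and U6 snRNA took 16.9% ± 1.67 of all reads, and antisense matches were 0.0120% of the matches on both strands. The plastid 4.5S rRNA alone took 8.43% ± 0.246, and 98.8% ± 0.261 of its reads ended at its 3' end. Its leading fragment, CTAACAGACCGGTAGACTTGAAC at positions 81 to 103 of 103, was the most abundant 23-nt sequence with 39180 ± 2284 RPM. The forms of 21, 22 and 24 nt with the same 3' end, AACAGACCGGTAGACTTGAAC, TAACAGACCGGTAGACTTGAAC and CCTAACAGACCGGTAGACTTGAAC, reached 10670 ± 182, 9708 ± 157 and 4081 ± 945. The 18S rRNA took 6.03% ± 0.841 of reads with 1.11% ± 0.166 of them at its 3' end. The 5.8S rRNA took 0.827% ± 0.204, with 42.9% ± 6.58 at its 3' end, and the nuclear 5S rRNA took 0.270% ± 0.0761, with 72.2% ± 1.72. The plastid 16S and 5S rRNAs took 0.432% ± 0.106 and 0.351% ± 0.05005. U6 snRNA took 0.000776% ± 0.0000610.

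Of the 5 nuclear tRNAs, 3 left mostly 5' pieces. tRNA-Asp-GTC took 0.286% ± 0.0847 of reads, 93.4% ± 0.336 of which started at its 5' end and 90.2% ± 0.517 of which were 30 to 35 nt long. tRNA-Ala-AGC and tRNA-Arg-CCT, at 0.0654% ± 0.0155 and 0.0457% ± 0.0147, started at the 5' end in 91.6% ± 0.560 and 89.1% ± 2.51 of reads, but their most frequent lengths were 16 nt and 19 nt. tRNA-Gly-GCC, at 0.109% ± 0.0311, started at the 5' end in 25.9% ± 6.91 of reads and ended at the 3' end in 50.0% ± 3.33. tRNA-Glu-CTC, at 0.0294% ± 0.00285, started at the 5' end in 32.1% ± 2.04. The share of plastid tRNA-His-GTG was 0.0187% ± 0.00455. The listed nuclear tRNAs were 1.49-fold lower in 1V than in 1U, the listed nuclear rRNAs 1.25-fold lower and the plastid tRNA-His-GTG 1.42-fold higher. The listed plastid rRNAs were 1.06-fold lower in 1V, with 1.42-fold for 16S, 1.22-fold for 5S and 1.04-fold for 4.5S.

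Control miRNAs of other organisms gave the background of a family match. The 4 families known from Brassicaceae had 0 reads in 1U and 4 reads in 1V, and the 3 animal families had 0 reads in both. None of them had more than 3 reads in a library.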

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

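The test of the scaling of miR397, miR398 and miR408 was chosen after its result was seen, and the 23-nt pattern was restated by different sequences after its values were seen, with its test unchanged. Reads of 30 to 42 nt, longer than the Dicer products the comparisons rest on, made up 14.2% of library 1U and 13.2% of library 1V. They enter the structural RNA shares but not the family levels or the pairing.

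miR397, miR398 and miR408 were lower in library 1V than in 1U. The smallest of the 3 folds was 3.77 under TMM and DESeq2 size factors. Both scalings were computed over the same listed families and shifted all of them by -0.38 and -0.32 on the log2 scale. They could therefore only widen these folds, so the value does not test the scaling. A factor that moves all families alike leaves these 3 the lowest of the 34 tested. The runs of a library differed by at most 0.24 on the log2 scale for these families, so no single run carried the difference. Runs compared within a library cannot test an effect that both runs of a library share. Other sequences of the same length and GC count had a lowest median log2 change of -0.15, which argues against a bias of length or GC content. Among the log2 changes of those sequences, the most abundant sequences of miR397, miR398 and miR408 lay at percentiles 0.451, 0.796 and 1.67. The plants, the preparation and the sequencing of each library stay open, and no biological explanation was tested.

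Short reads were a larger share of run 2 than of run 1 in both libraries, with 22.3% against 21.6% at 15 nt in 1U and 26.04% against 24.9% in 1V. The shift at 15 nt lay almost all in CCCGGCCGTCGGGGC and GCCCGCGACGTCGCG, since without them (a split chosen after the values were seen) the shares were 3.51% against 3.47% in 1U and 3.194% against 3.198% in 1V. Within 15-nt reads the log2 change from run 1 to run 2 rose with each G or C in both libraries, with 0.0668 as the smaller slope. At a fixed GC count it changed by -0.0053 per nt in the library nearer to 0, so both a GC bias and a length bias between the runs stay open. The shares did not fall steadily with length. From run 1 to run 2, 24-nt reads fell from 19.5% to 19.1% in 1U and from 19.4% to 18.9% in 1V. Reads of 30 to 42 nt went from 14.14% to 14.16% in 1U and from 13.20% to 13.14% in 1V. No biological explanation was tested, since the runs share a library.

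The 23-nt class was second to the 24-nt class in different sequences. If 23-nt siRNAs were 24-nt siRNAs without their 3' last base, the share of 23-nt reads equal to such a shortened sequence would exceed the share equal to one without its 5' first base. Without the listed RNAs, these shares were 47.2% and 53.1% in 1V, a ratio of 0.888. In 1U they were 49.0% and 54.5%, a ratio of 0.899. By different sequences the shares were 17.2% and 23.3% in 1V and 17.3% and 22.8% in 1U. The predicted excess of 3' loss over 5' loss was absent. The comparison cannot exclude 3' loss, since the share without the 5' first base is itself a shortening and not a background. No biological explanation was tested.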

How the results depend on the processing

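The coefficient of variation without 3 families, 5' overhangs as the background of pairing and the 2 added plastid tRNAs were chosen after the data were seen. Of the changes of the 15 named families under other settings, 95 kept their direction and their side of 2-fold, 8 changed sign and 2, both of miR319, fell below 2-fold (0.95 under TMM, 0.86 with up to 1 mismatch). The match with 1 mismatch also takes miR159 reads without their first base as miR319, so the 0.86 may mix both families. Over all 34 tested families, 14 changed sign under TMM and 11 under DESeq2 size factors. The number of families over 2-fold stayed between 4 and 6 under all 9 alternatives, but not with the same families. tasiR-ARF passed 2-fold under TMM and DESeq2 size factors, miR160 star with up to 1 mismatch (log2 1.30), and miR395 and miR530 with no minimum, names chosen after their values were seen. Counting different sequences once gave 52.7% at 24 nt, 5.86% at 21 nt, a ratio of 9.01, 57.5% A at 24 nt, 37.1% T at 21 nt and pairing of 5.84% at 24 nt and 6.02% at 21 nt. Without structural RNAs the values were 22.7% at 24 nt, 8.51% at 21 nt, a ratio of 2.67, 62.7% A and 67.2% T. Without the 100 most abundant sequences they were 37.9%, 7.18%, 5.28, 62.2% and 41.7%. With at least 5 reads in both libraries they were 10.1%, 8.31%, 1.21 and 65.7% A, and with at least 5 reads pairing was 10.7% at 24 nt and 5.74% at 21 nt. Within 18 to 28 nt the shares were 37.9% and 15.3%, by the smaller denominator. Run 1 alone gave 19.5% at 24 nt, pairing of 11.5% at 24 nt and 7.47% at 21 nt, and coefficients of variation of 0.289 at 21 nt and 0.188 at 24 nt. Run 2 alone gave 18.99% at 24 nt, pairing of 12.2% and 7.94%, and a coefficient of 0.192 at 24 nt. Pairing of 21-nt reads was 18.7% without listed RNAs. Against 5' overhangs the pairing ratio was 1.10 at 24 nt and 2.24 at 21 nt. The miRNA share was 5.73% with exact sequences and 3.50% of all reads. Sharing at 24 nt was 30.3% at 999226 and 999839 reads, 63.7% without thinning and 47.1% between runs, and at 21 nt 81.0%, 89.6% and 85.9%. Structural RNAs took 14.8% of reads of 20 nt or more and 19.7% with the 2 tRNAs added. Chi-square per degree of freedom with at least 10 and at least 200 reads was 1.39 and 4.92 between the runs of 1U, 1.45 and 7.24 between those of 1V, and 6.62 and 96.5 between libraries. The coefficient of variation of families was 0.162 without miR397, miR398 and miR408. With at least 10 and at least 200 reads it was 0.274 and 0.302 at 21 nt and 0.196 and 0.196 at 24 nt, and with library totals 0.287 at 21 nt. Under TMM the log2 change was -0.030 for miR157, -0.018 for miR166, -0.17 for miR167, -0.27 for miR396 and -0.10 for miR403, and under DESeq2 size factors -0.11 for miR167, -0.21 for miR396 and -0.040 for miR403. Where no reason is given, the cause was not tested. A single library gave 19.1% to 19.3% at 24 nt, 7.57% to 7.98% at 21 nt, a ratio of 2.40 to 2.55, 61.5% to 61.9% A, 58.1% to 65.2% T, a miRNA share of 6.12% to 7.69%, pairing of 14.7% to 15.8% at 24 nt and 8.71% to 9.68% at 21 nt, and structural RNAs of 15.7% to 18.1%. The coefficient of variation and the sharing, chi-square and changes between libraries compare both libraries, so they have no value with 1 left out. No paired analysis was possible because the study has 1 group. Depth limits the counts of single sequences, since over all lengths 76.3% of the different sequences of 1U and 74.9% of those of 1V had a single read.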

Other observations

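The 2 further plastid tRNAs and the 15-nt sequences were chosen after the data were seen. Among the reads of 30 to 42 nt, 20.4% ± 1.43 matched the listed structural RNAs and 18.8% ± 6.72 matched 2 further plastid tRNAs. Plastid tRNA-Asn-GTT took 1.62% ± 0.232 of all reads, and 96.5% ± 0.443 of its reads started at its 5' end. Its leading form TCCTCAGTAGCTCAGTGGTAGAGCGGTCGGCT, of 32 nt, took 0.927% ± 0.161 of all reads. Plastid tRNA-Asp-GTC took 0.771% of reads in 1U and 1.65% in 1V, a 2.14-fold difference, and 98.9% ± 0.3501 of its reads started at its 5' end. Its leading form was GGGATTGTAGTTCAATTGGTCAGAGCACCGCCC, of 33 nt, with 0.213% in 1U and 0.726% in 1V.

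The plastid tRNAs were higher in 1V, by 1.22-fold for tRNA-Asn-GTT, while the listed nuclear tRNAs were 1.49-fold lower. The listed plastid rRNAs were 1.06-fold lower in 1V, so plastid RNAs did not all move the same way. A second 15-nt sequence, GCCCGCGACGTCGCG, took 2.21% ± 0.231 of all reads and matched none of the listed RNAs. CCGGTCGTCTCGTCC, at positions 678 to 692 of the listed 18S rRNA, took 0.897% ± 0.0299.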
